A study of Mus musculus with 8 samples.

How the data were processed

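Total RNA from whisker follicles of female ApcMin/+ mice was measured in 8 samples, 4 given vehicle and 4 given E7386. Per the labels' protocols, 50 ng of RNA was turned into Cy3-labelled cRNA, and each sample was hybridised to a 1-colour Agilent array. The scanner files hold intensities per spot that the authors made with Feature Extraction, version 11.5.1.1 per the file headers and version 11 per the submitters' processing notes. The processed signal used here is the background-corrected intensity of that program, per the file headers. The value table deposited by the authors holds log2 values of the same arrays. Its columns share the same sorted values, with a median of 5.31 in each column and the same rank order as the processed signal, so it was quantile normalised. The table is on the log2 scale and not centred per gene, as checked against the scanner values, and it was used as an alternative.

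Each array has 62976 spots, of which 59305 are for mouse transcripts, on 55681 probes. The 75th percentile of the processed signal ranged from 459.4 to 656.2 between arrays, and between 36461 and 38365 spots per array were well above background. Between 2 and 14 spots per array were marked as non-uniform by the scanner program and were set to missing, and 1 spot was saturated. The detection limit metric of the scanner program was out of its range on vehicle replicates 1 and 2 and on E7386 replicate 4. Correlations of normalised log2 values lay between 0.985 and 0.994 within groups, with no pair of identical arrays. All 8 arrays lie on 1 slide with 1 scan, so no slide or scan could be fitted as a block, and each group fills a row of its own.

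The main values are log2 of the processed signal minus each array's 75th percentile of it over the probes for mouse transcripts. Spots of the same probe were averaged. The scanner files pair probes with accessions, not with symbols, and the names of 27509 probes come from matching unversioned accessions to a RefSeq table of GRCm38.p6, out of 29150 probes with a RefSeq accession. The other 28172 probes keep the name in the file and are called unnamed. The array was designed on mm9, so no coordinates are given. For each gene the probe with the highest mean over all 8 arrays was used, and a gene was kept where that probe was well above background on at least 3 of the 4 arrays of at least 1 group. This left 25353 genes, 16133 of them with a symbol. Of the called genes, 62 have other detected probes, 3 of these have a probe that moved the other way and 17 a probe with under 50% of the change.

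Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend or robust options, and adjusted with Benjamini-Hochberg at 0.05. Changes are E7386 minus vehicle. Lists of genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, over the 38 lists that have at least 3 measured members, with Benjamini-Hochberg adjustment over the lists. The list mean per array was compared with an exact two-sided permutation test. The lists, the test and the rule for naming genes were fixed before the data were examined. The rule names 14 genes of the pathway in every case, the 12 largest rises and the 12 largest falls among called genes whose groups of arrays do not overlap, leaving out names that are not symbols, and up to 4 members with the smallest p of each list, of which the text gives those of lists past the test, those of the Wnt target list and those past the threshold. Pdk4, Klf9, Mertk and Slc10a6 were named after their values were seen. Some genes that the rule names are not reported here. A gene that was not well above background on any array of a group has only a bound on its fold change.

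The test was tried on simulated data with the spread of the real genes, over 25326 genes without missing values and 20 runs of this comparison. It recovered 38.4% of genes changed by 0.5 on the log2 scale, 76.2% of those changed by 1 and 92.9% of those changed by 2, with 5.3% of the calls false. Camera found a list of 30 genes shifted by 0.4 in 20 of 20 runs with either correlation and called an unshifted list in 1. Each run held 200 genes changed by each size, and the simulated genes were drawn independently of each other. The rates above thus need not hold for another number of changed genes or for correlated genes. These runs therefore cannot show how camera at the preset correlation does on lists of correlated genes. In the real data the estimated correlation was 0.68 for the DNA replication list and 0.49 for the glucocorticoid list.

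Alternatives were the background correction and normalization, the authors' processed values, the filter on dim probes, the choice of probe, the variance model, array weights, spots marked by the scanner program, the replicate number as a block, the thresholds, the set test and leaving out each array. Added after seeing the data were normexp on the median signal with an offset of 50, a muscle score as a covariate, leaving out the 3 arrays with the lowest muscle signal, and setting population outlier spots to missing.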

Results

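Gene expression was measured in whisker follicles of female ApcMin/+ mice, which carry a truncating allele of Apc, a part of the complex that degrades beta-catenin. E7386 is an oral compound described as blocking the binding of beta-catenin to its coactivator CBP, and the comparison asks which genes differ in a hair-forming tissue after a long course of dosing. The E7386 group received 30 mg/kg by mouth in 2 doses per day for 4 cycles of 5 days with drug and 2 days without, starting at 8 weeks of age, and the other group received vehicle. Tissue was collected 6 h after the last dose. Each group has 4 samples, each hybridised to its own 1-colour array, and all 8 arrays lie on 1 slide, vehicle in row 1 and E7386 in row 2. Row and treatment therefore cannot be told apart in any difference given here. The share of spots for mouse transcripts well above background was 62.2% to 64.7% on vehicle arrays and 61.5% to 61.9% on E7386 arrays, without overlap, and the number of arrays limits the precision. The labels do not say whether the samples of a group came from separate mice, so the p-values measure only the spread between these samples.

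E7386 was followed by a rise in 191 genes and a fall in 93 genes among the 25353 genes tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). The largest rises among well-measured named genes were in Angptl4, a secreted inhibitor of lipoprotein lipase, at 5.64-fold, in Hdc, the enzyme that makes histamine, at 4.05-fold, in Wdr92 at 3.79-fold on 1 of its 2 detected probes, and in Fkbp5, a co-chaperone of steroid receptors, at 3.72-fold. The largest falls among genes measured on every array were in Ccn4, a matricellular protein first described as induced by Wnt1, at 2.90-fold, in Emilin3, an extracellular matrix protein, at 2.89-fold, and in Spon2, a secreted matrix protein, at 2.79-fold. Of the called genes, 75 rose and 26 fell at least 2-fold. Of the rises, 120 were in genes with a name and 71 in transcripts without one, against 86 named and 7 unnamed falls. The groups did not overlap for 2667 of the genes tested, where chance gives 2.86% of them. Rises made up 67.3% of the called genes, against 52.3% of the 258 called when each array was scaled by its median in place of its 75th percentile. They made up 56.7% of the 499 called when median signals were corrected with normexp, an alternative chosen after seeing the data. When 1 array was left out, their share ran from 65.8% (without E7386 replicate 1) to 81.0% (without vehicle replicate 3). The count dropped to 139, 107, 121 and 157 without vehicle replicates 1, 2, 3 and 4 and to 125, 88 and 100 without E7386 replicates 2, 3 and 4, and leaving out the 3 arrays with low muscle signal, also chosen after seeing the data, left 48.

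Among the largest rises, Angptl4 went from a normalised log2 signal of 2.00 ± 0.32 (SD, n = 4) with vehicle to 4.49 ± 0.53 with E7386, a log2 change of 2.49 (SE 0.27, adjusted p = 0.00768). Hdc rose by 2.02 (SE 0.14, adjusted p = 0.00103), Zbtb16, a transcription factor also known as PLZF, by 1.76 (SE 0.21, adjusted p = 0.0094), and Slc43a1, an amino acid transporter, by 1.66 (SE 0.16). Dio3, which inactivates thyroid hormone, rose by 1.63 (SE 0.16, adjusted p = 0.005). Fkbp5 rose by 1.89 (SE 0.33, adjusted p = 0.0409). Wdr92 was called at 1.92 (SE 0.14, adjusted p = 0.00103), but its other detected probe changed by 0.33. 4 further genes were dim with vehicle. Tmprss11a, a transmembrane serine protease, was well above background on 1 of 4 vehicle arrays and 4 of 4 E7386 arrays (log2 change 3.15, SE 0.56), Rgs17 on 2 and 4 (2.31, SE 0.35), and Bcat1, an enzyme of branched-chain amino acid metabolism, on 3 and 4 (1.76, SE 0.30). Tnfsf11, which encodes RANKL, was not well above background on any vehicle array and was at least 2.08-fold higher with E7386 (adjusted p = 0.0186). Such a bound raises each dim value to the lowest signal of any probe well above background on the same array. A higher floor would give a smaller bound. Normexp on median signals with an offset of 50 by construction shrinks the changes of dim genes. With it the 4 dim genes kept their calls, with changes of 0.97 for Tmprss11a, 0.59 for Rgs17, 0.51 for Bcat1 and 0.35 for Tnfsf11. Of 21 alternatives, Tmprss11a lost its call in 13, Bcat1 in 11, Rgs17 in 9 and Tnfsf11 in 5. Tmprss11a (adjusted p = 0.0465) lost it with quantile normalization (adjusted p = 0.0568), array medians (0.0527) and the authors' processed values (0.0573). With probes averaged Bcat1 was at 0.75 (adjusted p = 0.156).

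**Figure D1:**
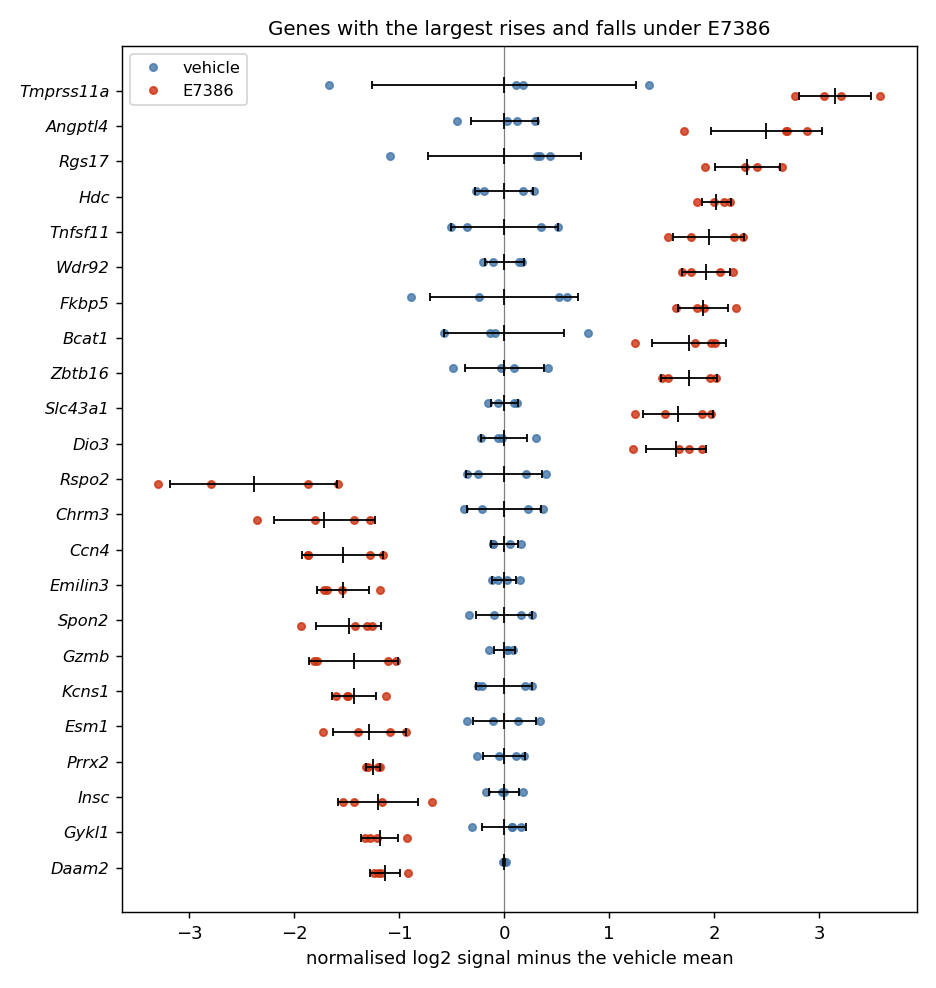
Normalised log2 signal of 23 genes with the largest rises and falls, as the difference from the vehicle mean of each gene. Points are single arrays, and ticks and bars are group means and SD. The 23 genes were picked among called genes whose groups of arrays do not overlap, so their separation holds by construction.

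Among the largest falls, Ccn4 fell by 1.54 on the log2 scale (SE 0.18, adjusted p = 0.00993), from 0.46 ± 0.13 (SD, n = 4) to -1.08 ± 0.38, and its other probe gave -1.50. Emilin3 fell by 1.53 (SE 0.13, adjusted p = 0.0019), Spon2 by 1.48 (SE 0.19, adjusted p = 0.0131), and Prrx2, a homeobox factor of mesenchyme, by 1.25 (SE 0.11, adjusted p = 0.00204). Daam2, a formin that takes part in Wnt signalling, fell by 1.13 (SE 0.10, adjusted p = 0.00473, n = 3 vehicle arrays). Its spot on vehicle replicate 4 was marked as non-uniform, and where that spot was kept its change was -2.60 without a call (adjusted p = 0.384), as it was with the authors' processed values (-2.63, adjusted p = 0.383). Esm1, a proteoglycan secreted by endothelium, fell by 1.28, Insc by 1.20 and Gykl1 by 1.19. Rspo2, a secreted protein that amplifies Wnt signals, was well above background on 4 of 4 vehicle arrays and on none with E7386, at least 2.27-fold lower (adjusted p = 0.0321), and Gzmb, a protease of cytotoxic lymphocytes, was at least 2.14-fold lower by the same measure (adjusted p = 0.0183). Chrm3, a muscarinic acetylcholine receptor, had a log2 change of -1.71 and was well above background on 2 of 4 E7386 arrays, and Kcns1, a potassium channel subunit, had -1.43 and was so on 1 of 4. With normexp the dim genes kept their calls with smaller changes. These were -0.47 for Rspo2, -0.37 for Gzmb, -0.50 for Chrm3, -0.42 for Kcns1, -0.57 for Insc and -0.43 for Gykl1. Of 21 alternatives, Chrm3 lost its call in 9, Rspo2 in 7, Gzmb in 6 and Kcns1 in 2. Of 22, Insc lost it in 9 and Gykl1 in 1. Angptl4, Hdc, Wdr92, Zbtb16, Slc43a1, Dio3, Ccn4, Emilin3, Kcns1, Prrx2, Gykl1, Daam2 and Dkk2 stayed past the threshold whichever array was left out. Each of the other called genes that are named lost its call without at least 1 array, and none changed sign.

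Genes induced by glucocorticoids rose as a group. All 15 measured members of that list had higher means with E7386, and the mean log2 change was 1.02 (median 0.71, camera adjusted p = 1.21e-11). The call does not hold with an estimated correlation between genes (adjusted p = 0.882 with an estimated correlation, unadjusted p = 0.0336). The mean signal of the list per array was 3.50 ± 0.15 (SD, n = 4) with vehicle and 4.52 ± 0.29 with E7386, with no overlap (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.362 after adjustment over the 38 lists). 6 members rose past the threshold over all genes and 10 adjusted over the list alone. They include Angptl4, Zbtb16 and Fkbp5, above, and Tsc22d3, an anti-inflammatory mediator also called GILZ, which rose by 0.82 (SE 0.11, adjusted p = 0.0154). Lcn2, an iron-binding defence protein, rose by 1.52 (SE 0.27, adjusted p = 0.0451), and Klf9 rose by 0.93 (SE 0.16, adjusted p = 0.046). Of the 8 fits that leave out an array, Angptl4 and Zbtb16 kept their calls in 8 and Tsc22d3 in 4. Fkbp5 and Lcn2 each kept theirs in 1 and Klf9 in 0. Pdk4, named like Klf9 after its values were seen, had a change of 2.83 that missed the threshold (SE 0.72, adjusted p = 0.121) and passed it with the muscle score as a covariate (2.96, adjusted p = 0.0171), an alternative chosen after seeing the data.

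Canonical Wnt target genes did not shift as a group. Of the 22 measured members, 0 rose and 1 fell over all genes, and the same numbers passed adjusted over the list alone. The mean log2 change was 0.0012, the median -0.005 and the direction of the test down (camera adjusted p = 0.874, adjusted p = 0.984 with an estimated correlation), so mean and median differ in sign. At an unadjusted p under 0.05, the 2 members Ccnd1 and Znrf3 stood out, with Znrf3 at -0.29 (SE 0.10, adjusted p = 0.205). Ccnd1, which encodes cyclin D1, was the member that fell, by 0.79 on the log2 scale (SE 0.12, adjusted p = 0.0294), from 3.76 ± 0.13 (SD, n = 4) to 2.97 ± 0.22. Axin2, the feedback inhibitor often used as a readout of the pathway, differed by -0.15 (SE 0.10, adjusted p = 0.532) on its brighter probe and 0.20 on the other. Changes short of the threshold were 0.0076 for Lef1 (SE 0.22), -0.018 for Nkd1 (SE 0.25, and -0.68 on its other probe), 0.20 for Notum (SE 0.11), 0.67 for Sp5 (SE 0.37, well above background on 3 of 4 vehicle arrays), 0.23 for Apcdd1 (SE 0.16), 0.11 for Lgr5 (SE 0.10), -0.042 for Myc (SE 0.12), 0.21 for Twist1 and 0.24 for Sp8. Ctnnb1, which encodes beta-catenin, differed by -0.095 (SE 0.067), Crebbp, which encodes CBP, by -0.0052 (SE 0.39), Ep300 by 0.0025 (SE 0.13) and Apc by 0.10 (SE 0.12), all with adjusted p of 0.55 or more. The call of Ccnd1 was kept in 1 of the 8 fits that leave out an array, the one without E7386 replicate 1, and its adjusted p ranged from 0.0311 to 0.0991 with log2 changes from -0.87 to -0.71.

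**Figure D2:**
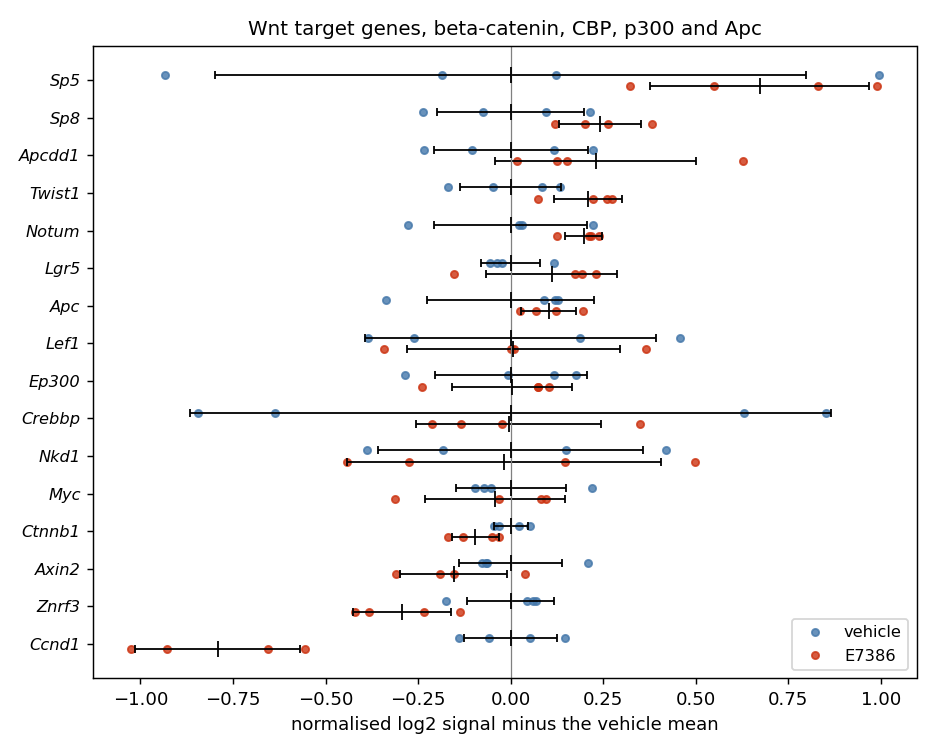
Normalised log2 signal of the named Wnt target genes and of Ctnnb1, Crebbp, Ep300 and Apc, as the difference from the vehicle mean of each gene. Points are single arrays, ticks and bars are group means and SD, and of these genes the 2 groups of arrays separate for Ccnd1, which fell by 0.79.

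Ligands, receptors and other parts of the Wnt pathway shifted down by a small amount, with a mean log2 change of -0.12 over 58 measured genes (median -0.096, camera adjusted p = 0.0429, exact two-sided permutation p = 0.0286, and 0.362 after adjustment over the 38 lists). The call does not hold with an estimated correlation (adjusted p = 0.882 with an estimated correlation). Of these genes 1 rose and 1 fell, over all genes and adjusted over the list alone. Dkk2, a secreted Wnt modulator, rose by 0.84 (SE 0.09, adjusted p = 0.00784), and Rspo2 is the one that fell. Rspo1 was at -0.39 (SE 0.11, adjusted p = 0.14) and Wnt10a at -0.40 (SE 0.11, adjusted p = 0.149). The shift of the list lost its call without vehicle replicate 3 (mean -0.11, adjusted p = 0.185), without vehicle replicate 4 (-0.12, 0.0995), without E7386 replicate 1 (-0.12, 0.061) and without E7386 replicate 4 (-0.097, 0.128). It also lost it with normexp on median signals (-0.076, 0.203), quantile normalization (-0.13, 0.142), the authors' processed values (-0.13, 0.143), detection required on all 8 arrays (-0.078, 0.103) and array weights (-0.12, 0.0577).

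Genes of DNA replication fell together. The mean log2 change of 29 measured genes was -0.36 (median -0.29, camera adjusted p = 4.46e-12, and adjusted p = 0.882 with an estimated correlation, which ends the call). 28 of the 29 had lower means with E7386, 2 passed the threshold over all genes and 14 adjusted over the list alone. Mcm2, a subunit of the replicative helicase, fell by 0.72 (SE 0.12, adjusted p = 0.0395), and Cdc6, which loads that helicase, fell by 0.74 (SE 0.13, adjusted p = 0.0412), or by 0.43 with normexp. Mcm5 was at -0.66 (adjusted p = 0.0838) and E2f1 at -0.77 (adjusted p = 0.0858), both short of the threshold. The mean signal of the list was 1.19 ± 0.10 (SD, n = 4) with vehicle and 0.83 ± 0.19 with E7386 (exact two-sided permutation p = 0.0286, and 0.362 after adjustment over the 38 lists). Mitosis genes, 30 measured, had a mean of -0.089 that did not pass (camera adjusted p = 0.176), and Birc5 was at -0.12 (SE 0.18). The difference between the scores of both lists changed by -0.27 (exact two-sided permutation p = 0.0286, unadjusted). That p is the smallest that 4 against 4 can give, and this difference was not among the planned tests. Without vehicle replicate 4, E7386 replicate 1 or E7386 replicate 2 the mitosis list passed, at -0.19, -0.18 and -0.12. It also passed with no detection filter (-0.089, adjusted p = 0.03) and, among alternatives chosen after seeing the data, with the muscle score as a covariate (-0.11, adjusted p = 0.0206) and without the 3 arrays of low muscle signal (-0.20, adjusted p = 0.00028). Mcm2 kept its call in 1 of the 8 fits that leave out an array and Cdc6 in 0.

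Cholesterol synthesis genes also shifted down, by a mean of -0.27 over 21 measured genes (median -0.28, camera adjusted p = 8.22e-08, and adjusted p = 0.882 with an estimated correlation, which ends the call). The list means per array did not pass the exact two-sided permutation test (p = 0.0571). 1 member fell over all genes and 9 adjusted over the list alone. Lss, which encodes lanosterol synthase, fell by 0.48 (SE 0.08, adjusted p = 0.0363), a call lost in each of the 8 fits that leave out an array. The changes of Fdft1 (-0.45, adjusted p = 0.0564) and Mvd (-0.40, adjusted p = 0.0958) did not pass, and the other probe of Fdft1 gave 0.27. Of 22 alternatives, Fdft1 passed in 7 and Mvd in 2. Those of Fdft1 include quantile normalization (adjusted p = 0.0379) and the authors' processed values (adjusted p = 0.038).

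Keratin-associated proteins, the matrix proteins of the hair shaft, were higher as a list, and so were markers of sebaceous gland and of fat. The mean log2 change was 0.82 for 50 keratin-associated proteins (median 0.57, camera adjusted p = 5.72e-05), 0.25 for 19 sebaceous genes (median 0.16, adjusted p = 0.00275) and 0.47 for 16 fat genes (median 0.28, adjusted p = 0.0368), and each has an adjusted p = 0.882 with an estimated correlation. The exact two-sided permutation p of the list means was 0.0571 for sebaceous genes and 0.314 for fat genes. 0 keratin-associated proteins passed the threshold, over all genes or adjusted over the list alone. Their list means were 5.76 ± 1.07 (SD, n = 4) with vehicle and 6.58 ± 0.43 with E7386 (exact two-sided permutation p = 0.2), and the members with the smallest p were Krtap6-2 (3.29, SE 1.02), Krtap6-5 (2.32, SE 0.97), Krtap19-1 (4.17, SE 1.86, well above background on 2 of 4 vehicle arrays) and Krtap19-5 (2.40, SE 1.07). Vehicle replicates 3 and 4 had list means of 4.79 and 4.95, while vehicle replicate 1, at 6.28, lay next to the E7386 values of 6.29 to 7.21 and vehicle replicate 2 lay among them. Without vehicle replicate 4 the mean change was 0.56 (adjusted p = 0.0733), without vehicle replicate 3 it was 0.50 (adjusted p = 0.0483), and without vehicle replicate 2 it was 1.24. Among sebaceous genes 1 rose over all genes and 2 adjusted over the list alone. Dgat2l6 rose by 0.77 (SE 0.13, adjusted p = 0.0339), a call lost whichever array was left out, and Awat1 was at 0.57, Mogat1 at 0.52 and Acsbg1 at 0.35, short of the threshold. 0 fat genes passed by either count, with Plin4 at 1.55 (SE 0.38, adjusted p = 0.108), Pck1 at 1.35, Pnpla2 at 0.48 and Lipe at 0.27. The fat list lost its call without vehicle replicate 1 (mean 0.15, adjusted p = 0.364), E7386 replicate 3 (0.30, 0.168) or E7386 replicate 4 (0.41, 0.114), and also with no detection filter (0.47, 0.126), detection required on all 8 arrays (0.43, 0.102) and probes averaged (0.43, 0.0703). Muscle markers differed between arrays of the same group. Their list mean was 1.09 on vehicle replicate 1, 1.41 and 1.97 on E7386 replicates 1 and 2, and from 3.13 to 3.80 on the other 5 arrays, with group means of 2.89 ± 1.23 (SD, n = 4) for vehicle and 2.74 ± 1.24 for E7386.

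**Figure D3:**
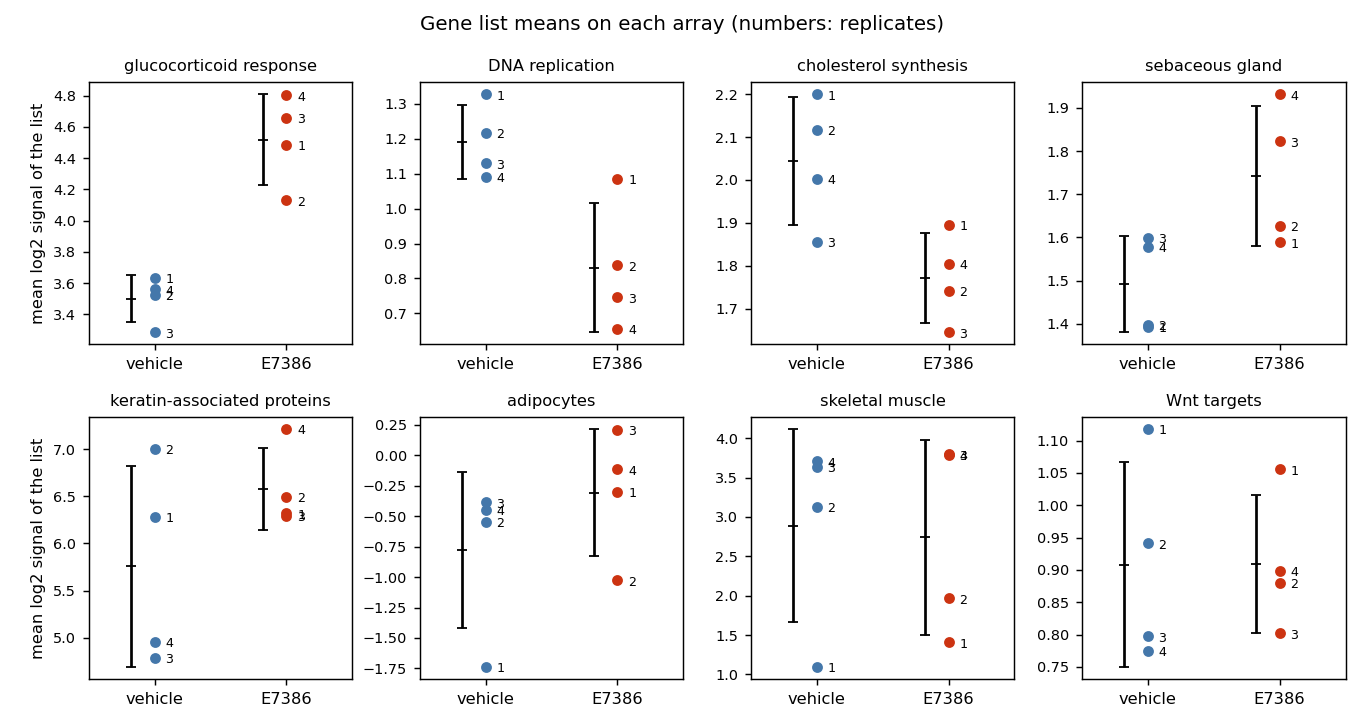
Mean normalised log2 signal of the genes of 8 lists on each array. Points are arrays with their replicate numbers, and ticks and bars are group means and SD. The groups separate for the glucocorticoid list (3.50 against 4.52) and narrowly for DNA replication (1.19 against 0.83). In the latter, E7386 replicate 1 is at 1.0856 and vehicle replicate 4 at 1.0905. Skeletal muscle spans from 1.09 to 3.80 within the groups.

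The 30 other lists did not pass the test, and their means follow. Among lists of the hair follicle and epidermis, mean log2 changes were 0.50 for hair shaft keratins and 0.0073 for inner root sheath (median -0.026). They were 0.0018 for hair matrix and shaft regulators, -0.044 for bulge stem cells and -0.14 for dermal papilla. They were 0.11 for outer root sheath and basal keratinocytes and 0.076 for epidermal differentiation. Among other cell types they were -0.15 for skeletal muscle, 0.15 for Schwann cells, 0.09 for Merkel cells, -0.076 for melanocytes, -0.095 for dermal fibroblasts and matrix, -0.099 for cartilage-like connective tissue, -0.024 for endothelium, -0.072 for red blood cells, 0.28 for neutrophils, -0.015 for macrophages (median 0.052), -0.38 for lymphocytes and 0.17 for mast cells. Signalling and stress lists were at -0.30 for Hedgehog, -0.048 for BMP and TGF-beta, -0.028 for Notch (median 0.0061), -0.16 for interferon response, 0.064 for the circadian clock, 0.043 for immediate early genes, 0.13 for p53 response, 0.041 for xenobiotic response, -0.0028 for the unfolded protein response, -0.038 for hypoxia and -0.089 for mitosis. Single members passed over all genes in some of these lists. Hdc is a mast cell gene, Lcn2 a neutrophil gene and Gzmb a lymphocyte gene. Trp53inp1, a p53 target, rose by 0.60 (SE 0.09, adjusted p = 0.0206), Cyp1b1, a cytochrome P450 induced through the aryl hydrocarbon receptor, by 0.82 (SE 0.14, adjusted p = 0.0395), and Col5a2, a fibrillar collagen, by 0.46 (SE 0.08, adjusted p = 0.0369). Cyp1b1 and Col5a2 lost their calls whichever array was left out. Adjusted over the list alone, 3 unfolded protein response genes rose and 5 fell, 3 p53 genes rose, 2 mast cell genes rose, 2 xenobiotic genes rose and 1 fell, 1 lymphocyte gene rose and 2 fell, 1 Hedgehog gene rose and 1 fell, 1 fibroblast gene rose and 1 fell, 1 clock gene fell, and 1 gene each rose among Merkel cells, Schwann cells and neutrophils. Some lists passed when 1 array was left out. Without vehicle replicate 1 these were hair shaft keratins (0.67), endothelium (-0.11), interferon response (-0.22) and skeletal muscle (-0.75), without vehicle replicate 2 hair shaft keratins (0.73), and without vehicle replicate 4 dermal fibroblasts (-0.15). Without E7386 replicate 1 they were lymphocytes (-0.58) and outer root sheath (0.17), without E7386 replicate 2 interferon response (-0.41), Hedgehog (-0.40), Schwann cells (0.21) and cartilage-like tissue (-0.15), and without E7386 replicate 3 hair shaft keratins (0.55). With no detection filter Hedgehog (-0.30, adjusted p = 0.03), dermal fibroblasts (-0.095, 0.0347), endothelium (-0.031, 0.0391), interferon response (-0.15, 0.0232) and lymphocytes (-0.38, 0.03) passed, and with array medians hair shaft keratins did (0.42, 0.0241). Without the 3 arrays of low muscle signal, chosen after seeing the data, Hedgehog (-0.48), Schwann cells (0.27), endothelium (-0.094), hair shaft keratins (0.80), interferon response (-0.50), lymphocytes (-0.76), macrophages (-0.30) and outer root sheath (0.19) passed.

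**Figure D4:**
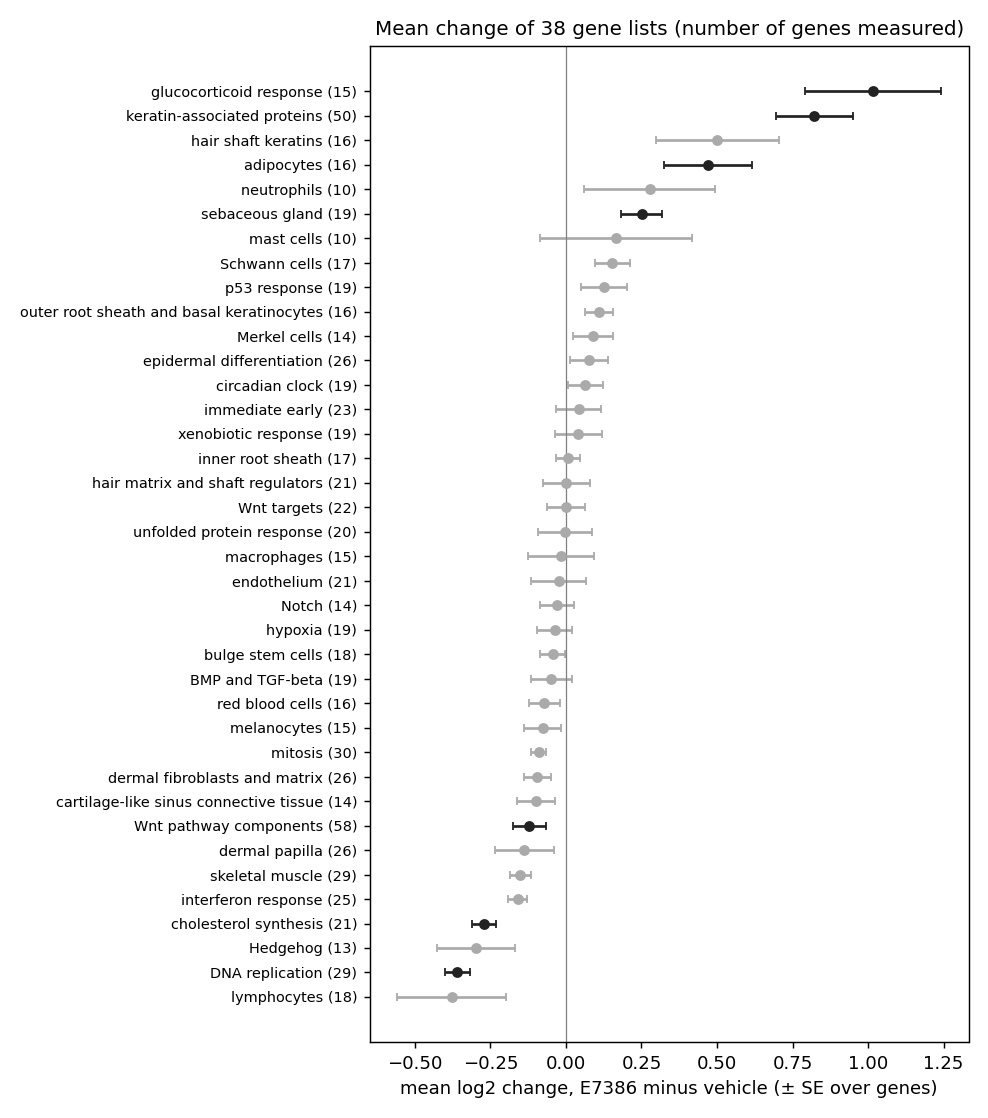
Mean log2 change of the measured genes of 38 lists, E7386 minus vehicle, with bars for the SE over the genes of a list and the number of genes in brackets. Black points are the 7 lists past the camera test, led by the glucocorticoid list at 1.02 and, on the other side, DNA replication at -0.36, and Wnt targets lie at 0.0012.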

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

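In 14 of 217 groups of 4 arrays checked, over list means and named genes, a single array lay far from the other 3 by a test of its gap relative to the range. That is 6.45%, and chance gives about 1 in 20. All values are normalised log2 signals, and highest and lowest are meant among the 4 arrays of the same group.

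The mean of the fat genes was -1.74 on vehicle replicate 1, against -0.545 to -0.385 on the other vehicle arrays. Hair shaft keratins had a mean of 6.82 on E7386 replicate 4, against 6.23 to 6.26. Interferon response genes had a mean of 0.32 on E7386 replicate 2, where the other 3 arrays had -0.82 to -0.63.

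Among the genes that rose, Angptl4 was at 3.71 on E7386 replicate 2, against 4.68 to 4.88 on the other 3, and Rgs17 was at -6.76 on vehicle replicate 4, against -5.37 to -5.23. Klf9 was at 2.11 on vehicle replicate 3, against 2.35 to 2.38 on the other vehicle arrays. Among Wnt genes, Axin2 (-0.54) and Myc (0.83) were the highest of the vehicle arrays on replicate 1, Apc (-2.67) and Znrf3 (-2.14) were the lowest of the vehicle arrays on replicate 2, and Lgr5 (0.73) was the lowest of the E7386 arrays on replicate 4. Among the E7386 arrays, Rspo1 was highest on replicate 1 (2.94), Ep300 was lowest on replicate 4 (-1.02), and Acsbg1 was highest on replicate 4 (3.11).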

How the results depend on the processing

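The alternatives with normexp on median signals, with a muscle score, without the 3 arrays of low muscle signal and with population outlier spots missing were chosen after seeing the data. None of the 37 named genes past the threshold changed sign under any alternative run. Of their 806 values under alternatives, 569 stayed past the threshold and 237 did not, and 21 of 746 values of the other named genes passed. For the 37 lists other than Wnt targets, 808 of 923 values kept their direction and their side of the threshold, 30 lost the call, 34 gained it and 51 changed sign. The planned normexp correction of mean signals was not run, since the columns used here hold no mean signal, and a slide or scan block could not be fitted with 1 slide and 1 scan. Unless stated otherwise, the cause of a difference was not tested. The lowest signal of a spot well above background was 11.3 to 16.6 on an array, before scaling, which limits what can be measured in dim genes.

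The count of genes changed was 499 with normexp on median signals, where the count of genes lower with E7386 was 216. With no detection filter it was 153 of 37018 genes tested, and the counts of genes higher with E7386 and of genes lower with E7386 were 112 and 41. With the muscle score as a covariate it was 568 (315 higher and 253 lower), of which 282 were among the 284. Without the 3 arrays of low muscle signal it was 48 (36 and 12), of which 37 were among the 284, from fewer samples. With a 2-fold change required it was 101 (75 and 26), and at an adjusted p under 0.1 it was 689 (397 and 292), both by construction. With trend and robust options 158 genes were lower. Leaving out 1 array gave 88 to 240 genes, 67 to 158 higher and 21 to 82 lower, from fewer samples.

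With the replicate number as a block 59 genes passed (50 higher and 9 lower), of which 52 were among the 284. Of the 37 named genes past the threshold 8 passed with the block, and of the 13 that stayed past it whichever array was left out 6 did, Hdc, Wdr92, Slc43a1, Emilin3, Prrx2 and Gykl1. With the block 8 lists passed, with mitosis as the added one (-0.089, adjusted p = 0.0209), and Pdk4 passed as well (adjusted p = 0.0495). In a check of pairing, same-numbered samples correlated in their deviations from the group means at 0.487, -0.165, 0.287 and 0.18. Vehicle replicates 2 and 4 correlated best with E7386 replicates 4 and 3, so the numbers were not taken to pair the samples. Some values did follow the number in both groups. The DNA replication mean fell from replicate 1 to replicate 4, from 1.33 to 1.09 with vehicle and from 1.09 to 0.66 with E7386. The muscle mean was lowest on replicate 1 in both groups (1.09 and 1.41). A link between same-numbered samples therefore stays open. Same-numbered arrays also lie in the same slide column, so the block holds any effect of the column as well.

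The number of gene list shifts was 12 with no detection filter, 17 without the 3 arrays of low muscle signal, 0 with an estimated correlation and 0 with fry, and 5 to 12 when 1 array was left out. The Wnt target list did not pass under any alternative, with adjusted p from 0.473 to 0.984.

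The signs of some small changes differed between alternatives. The skeletal muscle list passed in its new direction without the 3 arrays of low muscle signal (adjusted p = 0.00247), and those arrays were left out for their muscle signal, 1 of them from the vehicle group and 2 from the E7386 group. With normexp on median signals the change was -0.0038 for Ep300, 0.013 for Nkd1, -0.019 for Wnt targets and -0.032 for inner root sheath. With quantile normalization the change was -0.017 for Ep300, -0.0084 for Wnt targets and -0.028 for inner root sheath. With array medians the change was -0.074 for Ep300, -0.069 for Lef1, -0.076 for Wnt targets, -0.014 for circadian clock, -0.0010 for epidermal differentiation, -0.075 for hair matrix and shaft regulators, -0.034 for immediate early, -0.070 for inner root sheath and -0.036 for xenobiotic response. With the authors' values the change was -0.018 for Ep300, -0.0088 for Wnt targets and -0.028 for inner root sheath. With no detection filter the change was 0.021 for hypoxia. With detection on all 8 arrays the change was -0.031 for Wnt targets. With probes averaged the change was 0.024 for Axin2, 0.17 for Birc5 and -0.0032 for Wnt targets. With array weights the change was 0.036 for Crebbp, -0.056 for Lef1, -0.019 for Wnt targets, -0.015 for hair matrix and shaft regulators, -0.032 for inner root sheath and 0.015 for skeletal muscle. With the muscle covariate the change was 0.043 for Crebbp, -0.0050 for Ep300, -0.028 for Lef1, -0.013 for Wnt targets, -0.018 for hair matrix and shaft regulators and -0.013 for inner root sheath. Without the 3 arrays of low muscle signal the change was -0.029 for Ep300, -0.015 for Lef1, 0.17 for Nkd1, 0.11 for Myc, -0.11 for epidermal differentiation, -0.049 for hair matrix and shaft regulators, -0.029 for mast cells, -0.053 for neutrophils, 0.30 for skeletal muscle and 0.027 for unfolded protein response. With keratin genes out of the background the change was -0.0097 for inner root sheath.

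When 1 array was left out, the ranges that crossed 0 were -0.048 to 0.071 for Wnt targets, -0.11 to 0.033 for endothelium, -0.018 to 0.20 for epidermal differentiation, -0.054 to 0.075 for hair matrix and shaft regulators, -0.092 to 0.096 for inner root sheath, -0.11 to 0.092 for macrophages, -0.23 to 0.049 for melanocytes, -0.28 to 0.23 for red blood cells, -0.75 to 0.29 for skeletal muscle, -0.031 to 0.017 for unfolded protein response, -0.034 to 0.089 for xenobiotic response, -0.29 to 0.28 for Crebbp, -0.093 to 0.083 for Ep300, -0.010 to 0.15 for Apc, -0.12 to 0.16 for Lef1, -0.19 to 0.12 for Nkd1 and -0.087 to 0.049 for Myc.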

Other observations

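The tests of the second glucocorticoid list, of the fasting and PPAR-alpha list and of the muscle covariate were added after the first results were seen, with their outcomes stated before their values were computed, and the tests on unnamed transcripts and on dermal genes were chosen only after the result was seen.

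Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes as the 284 called, the real one, and the highest of the others gave 0. That share is the smallest these 35 splits can give, so it does not exclude a chance assignment of the arrays. The other splits mix the groups, which puts any difference between them into the spread within groups, so their 0 calls add little. Slide row and treatment cannot be told apart, since each group fills 1 row, and a row effect stays open for every difference.

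The glucocorticoid list rose by a mean of 1.02. With the muscle score as a covariate its mean was 1.02. That fit could hardly have come out otherwise, since the muscle score differed little between the groups (2.89 ± 1.23 with vehicle and 2.74 ± 1.24 with E7386). The close group means themselves leave little difference in muscle RNA to account for the rise. A wider response of the glucocorticoid receptor is a hypothesis, and 16 other induced genes, chosen to leave out those already seen among the strongest changes, had a mean of 0.43 (camera p = 7.94e-07, p = 0.0511 with an estimated correlation, exact two-sided permutation p = 0.0286), with Mertk (0.63, adjusted p = 0.00982) and Slc10a6 (0.68, adjusted p = 0.046) past the threshold. A fasting-like state is another hypothesis that could raise Angptl4 and Pdk4, and 24 measured PPAR-alpha and FOXO targets, chosen the same way, had a mean of 0.27 (camera p = 5.07e-05, p = 0.0284 with an estimated correlation, exact two-sided permutation p = 0.0286), with 0 genes past the threshold. Only a fall of a list past the camera test was set to count against its hypothesis. Both lists moved as these hypotheses need, so the tests do not separate them, and corticosterone, food intake and body weight were not analysed here.

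Among bright genes with a called rise above 1.6 on the log2 scale, 20 were unnamed transcripts, with rises from 1.61 to 2.27, and 5 were named genes, Wdr92 among them. The deviations of the unnamed ones from the group means had a median pairwise correlation of 0.872, against 0.538 for the 5 named genes, and about 1 in 20 of 1000 random sets of bright genes exceeded 0.296. The called probe of Wdr92 correlated with them at a median of 0.915, while its other probe, well above background on 8 of 8 arrays, changed by 0.33. These values are consistent with probes that bind one shared sequence, a hypothesis tested on the data that raised it, and a common regulation of separate transcripts stays open, since probe sequences were not used here. The count of unnamed rises could therefore be larger than the number of separate transcripts.

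The falls of Ccn4, Rspo2, Emilin3 and Prrx2 might come from fewer dermal cells in the E7386 samples. The dermal fibroblast list had a median of -0.082 (SD 0.23 over its genes), against falls of 1.25 to 1.54 for Prrx2, Emilin3 and Ccn4. A general loss of such cells as large as those falls is thus not seen in this list. The median was -0.73 for all 86 called falls in genes with a symbol, of whatever cell type. That comparison cannot decide the question, since those genes were selected for their falls. The dermal papilla list had a mean of -0.14 and a median of -0.098, and did not pass (camera adjusted p = 0.281). Of its 26 measured genes, 17 had negative and 9 positive changes (exact two-sided permutation p of the list means 0.0571). A smaller general loss, a loss of one kind of dermal cell, or a change of expression within cells, stays open.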
